A study of Mus musculus with 18 samples.

How the data were processed

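Poly(A)-selected, strand-specific libraries were sequenced from RNA of what the extraction protocol in the labels calls organoids, per the labels' protocols. The authors deposited 1 table with a row per gene and a column per library, for 18 libraries in 4 diet groups. Each column was matched to its sample by the library name in the sample's description. The values are estimated counts that the authors deposited as whole numbers. They were made with Salmon 1.3.0 and the build was mm10, per the submitters' processing notes. The annotation release, the summing of transcripts to genes and any filter are not given in the sources used here. Salmon divides reads that match several transcripts among them by a statistical estimate, so the counts of near-identical gene copies are uncertain. No values needed rounding, and no column of per-sample values was left unused. The table has 54354 rows, of which 1243 carry no gene symbol, and 94.7% of the row identifiers occur in the GENCODE M21 annotation of the same build, from which coordinates were taken.

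Samples were grouped by the diet in the labels. The labels do not say that the libraries of a group come from separate animals or cultures, so p-values measure the spread between these libraries, which may be technical. No columns were identical. Library totals ranged from 499774 to 12841275, so 3 counts correspond to 5.73 CPM in the SF_CD library 5, among the shallowest, and 0.234 CPM in the deepest. Confidence intervals and floors cover counting error only.

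The test was edgeR's quasi-likelihood test (edgeR 4.0.16, robust, in R 4.3.3) with TMM normalization and the filterByExpr filter, with Benjamini-Hochberg adjustment and a threshold of 0.05. The design fixed before the data were examined put all 18 libraries in 1 model. The row labels of the CD and HFD columns were then found not to name the genes of their counts, so that such a model would mix different genes in a row. The values reported therefore come from models of only the libraries of the groups compared, which was among the alternatives fixed beforehand. This change of the main model was made after the data and both counts had been seen, and the counts of the planned model are given beside the others. The main count of HFD against CD rose from 4 to 453 with this change, and that of SF_HFD against SF_CD fell from 109 to 38. The planned interaction and the comparisons of serine-free with other diets are not reported. A fit with the CD and HFD rows taken in the order of the sorted symbols, interaction included, was examined after the data were seen. It is not reported, because genes would be named from the place of their rows. Standard errors were derived from the log2 fold change and the F statistic. CPM are TMM-normalised unless said otherwise.

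Gene lists (38 lists, 800 entries) were written before the data were examined, from general knowledge. Lists with at least 4 measured genes (30 lists) were tested with camera (limma 3.58.1) at its preset correlation of 0.01, with camera at an estimated correlation and with fry. The other 8 lists had at most 3 measured genes. The rule for named genes, fixed at the same time, took the 10 genes with the largest increase and the 10 with the largest decrease among those called, with a mean log2 CPM of at least 1 and no overlap between groups. It added in each list up to 4 called members or, with none, up to 2 of the most abundant members, and 16 genes chosen in advance. The mean was taken over the 10 serine-free libraries. Genes at 0 in a group are given as a bound against 3 counts over the group. Scores per library were the mean log2 CPM (prior count 2) over the measured members of a list. Ratios on 1 to 3 counts have exact 95% binomial intervals.

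The test was run on simulated counts with 200 changed genes, drawn from the real means and spreads. The changed genes were taken only from those above a minimum mean count, so recovery among rarer genes was not measured. For SF_HFD against SF_CD (11506 genes), 42.4% of genes with a 4-fold change and 0% of those with a 2-fold change were recovered, and 3 unchanged genes were called. For HFD against CD (10014 rows), the shares were 88% and 29%, with 11 unchanged rows called. Alternatives were RLE and upper quartile normalization, no filter and a stricter filter, DESeq2 1.42.0, limma-voom with sample quality weights, all 18 libraries in 1 model, a replicate block, leaving out each library in turn and a 2-fold minimum. A model without the 3 libraries under 1000000 counts was added after seeing the data. Some genes that the rule takes are not reported here.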

Results

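Gene expression was measured by poly(A)-selected, strand-specific RNA sequencing of mouse samples. The extraction protocol in the labels names organoids, which are cultures of epithelial cells grown as small three-dimensional structures. The design text of the series instead describes live cells sorted from colons or colon tumors for single-cell sequencing, and the sources used here do not settle which of these the libraries come from. The labels give colon as the tissue, tumor as the cell type and a wild type genotype. The 18 libraries fall into 4 groups by diet. The control diet (CD) had 3 libraries, the high fat diet (HFD) had 5, the serine-free control diet (SF_CD) had 5 and the serine-free high fat diet (SF_HFD) had 5. The title of the series names ceramides and a revival stemness program, and the design pairs a high fat diet with its control once with and once without dietary serine, an amino acid from which ceramide synthesis starts. Total counts ranged from 4595404 to 8173352 in CD, from 3513703 to 7235611 in HFD, from 499774 to 12841275 in SF_CD and from 727610 to 12146933 in SF_HFD.

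**Figure D1:**
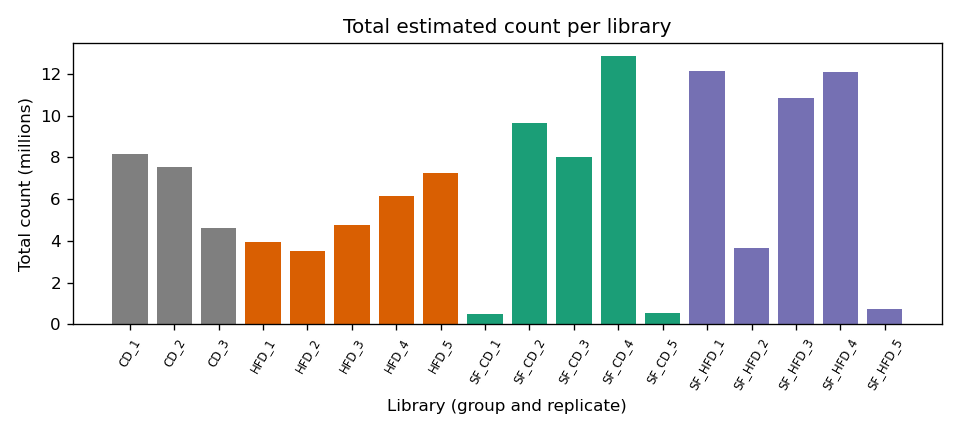
Total estimated count (y axis, in units of 1000000 counts) of each of the 18 libraries (x axis), coloured by group. The SF_CD libraries 1 and 5 and the SF_HFD library 5 each held under 1000000 counts, and the SF_CD library 4 held 12841275.

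In the serine-free libraries, SF_HFD was compared with SF_CD to show the effect of the high fat diet in the absence of serine. Of 11780 genes tested in the 10 libraries, 18 were higher and 20 lower in SF_HFD at an adjusted p under 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg). The values of the 2 groups did not overlap for 36 of the 38 genes. Over all genes tested, 3.65% had groups that did not overlap, against 0.794% from chance alone. The contractile genes Myl9, Acta2 and Actg2 and the matrix genes Lox, Postn and Col5a2 were among those that rose, and Zg16 and Muc2, genes of goblet cells, were among those that fell.

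Myl9, Acta2 and Actg2 were higher in every SF_HFD library than in any SF_CD library. Myl9, a myosin light chain of smooth muscle (mm10 chromosome 2, 156775420 to 156781658), was at 46.9 ± 7.90 CPM in SF_HFD and 1.77 ± 1.23 CPM in SF_CD (SD, n = 5 each), a log2 fold change of 4.49 ± 0.48 (SE, edgeR adjusted p = 0.000156). Acta2, the smooth muscle actin (chromosome 19, 34241090 to 34255590), was at 97.6 ± 18.1 CPM against 6.79 ± 5.45 CPM, with a log2 fold change of 3.97 ± 0.55 and an edgeR adjusted p of 0.00232. Actg2, the enteric smooth muscle actin, was at 40.3 ± 9.10 CPM against 1.54 ± 2.24 CPM (edgeR adjusted p = 0.0159). The SF_CD mean was 0.598 CPM without the SF_CD library 2. The call of Actg2 was lost without the SF_CD library 1 (edgeR adjusted p = 0.0582), the SF_HFD library 2 (0.0564) or the SF_HFD library 5 (0.0532). It was also lost without the 3 libraries under 1000000 counts (edgeR adjusted p = 0.159). The log2 fold change in these settings was 4.25 to 4.49. Of the 13 genes written for the smooth muscle and pericyte list, 7 were measured, and 3 of these rose over all genes tested. Adjusted over the list alone, 7 rose. The median log2 fold change of the list was 4.08 (camera adjusted p = 3.37e-23 with a preset correlation). The adjusted p was 0.0516 with an estimated correlation, and fry gave 0.00172.

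Lox, Postn and Col5a2 rose from low levels. Lox, which crosslinks collagen (chromosome 18, 52516067 to 52529867), was at 14.3 ± 3.26 CPM in SF_HFD and 0.728 ± 0.755 CPM in SF_CD, a log2 fold change of 4.49 ± 0.58 (edgeR adjusted p = 0.00121). Postn, a matrix protein of fibroblasts, was at 7.52 ± 0.922 CPM against 0.668 ± 0.744 CPM (log2 fold change 3.84), and Col5a2, a fibrillar collagen chain, was at 12.1 ± 2.17 CPM against 0.699 ± 0.792 CPM (log2 fold change 3.49). The SF_CD means of Lox and Postn were 0.423 and 0.348 CPM without the SF_CD library 5, and that of Col5a2 was 0.406 CPM without the SF_CD library 2. In the fibroblast list, 10 of 19 genes were measured and 2 rose, Postn and Mfap5, a microfibril protein with a log2 fold change of 2.80 whose call was lost in 9 of 19 other settings. Adjusted over the list alone, 6 rose. The list median was 1.93 (camera adjusted p = 2.03e-08), and the adjusted p was 0.216 with an estimated correlation. The fry adjusted p of the fibroblast list was 0.0588. Of the 25 genes of the epithelial-mesenchymal transition list, 16 were measured and 1 rose. Adjusted over the list alone, 3 rose and 1 fell, and camera gave an adjusted p of 0.0658 (adjusted p = 0.651 with an estimated correlation). With the preset correlation, this list was called without the SF_CD library 5 (camera adjusted p = 0.0109), the SF_HFD library 1 (0.0325), the SF_HFD library 2 (0.0442) or the 3 libraries under 1000000 counts (0.0143). Ctla2a, a protease inhibitor, also rose (26.4 ± 4.94 CPM against 2.77 ± 1.93 CPM). Ido1, which degrades tryptophan, had a log2 fold change of 6.74 ± 1.34 (edgeR adjusted p = 0.0477), but its SF_HFD libraries varied widely (81.1 ± 111 CPM, with a mean of 34.0 CPM without the SF_HFD library 4) and its call was lost in 12 of 19 other settings.

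Zg16, Muc2, Mptx1 and Sycn were low in SF_CD and lower in SF_HFD. Whether RNA from another source gave their low SF_CD counts was not tested. Zg16, a lectin of goblet cell granules (chromosome 7, 127050156 to 127087328), was at 16.4 ± 13.7 CPM in SF_CD and had a single count in all SF_HFD libraries together. The SF_CD library 5, with under 1000000 counts and 14.5% ribosomal RNA, was at 40.9 CPM, and the mean of the other 4 was 10.3 CPM. The ratio of its pooled counts was 387 (exact 95% interval 68.9 to 15332). Muc2, the main gel-forming mucin of the colon, was at 3.11 ± 0.611 CPM in SF_CD and also had 1 count in SF_HFD, a ratio of 118 (interval 20.6 to 4698). Mptx1, a pentraxin of the intestinal epithelium, had 436 counts in SF_CD and 0 in SF_HFD, which makes it at least 182-fold lower against a floor of 3 counts over the group. Sycn, a protein of secretory granules, had 280 counts against 0, at least 117-fold lower. Spink1, a trypsin inhibitor, fell by 5.13 on the log2 scale and Ceacam10 fell by 4.75. The edgeR adjusted p of Ceacam10 was 0.0568 without the SF_HFD library 2 and 0.107 without the 3 libraries under 1000000 counts. In the goblet list, 13 of 18 genes were measured, 2 fell and none rose, and adjusted over the list alone 2 fell. The list median was -0.69 (camera adjusted p = 3.12e-05), with an adjusted p of 0.203 with an estimated correlation. The fry adjusted p of the goblet list was 0.0588.

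**Figure D2:**
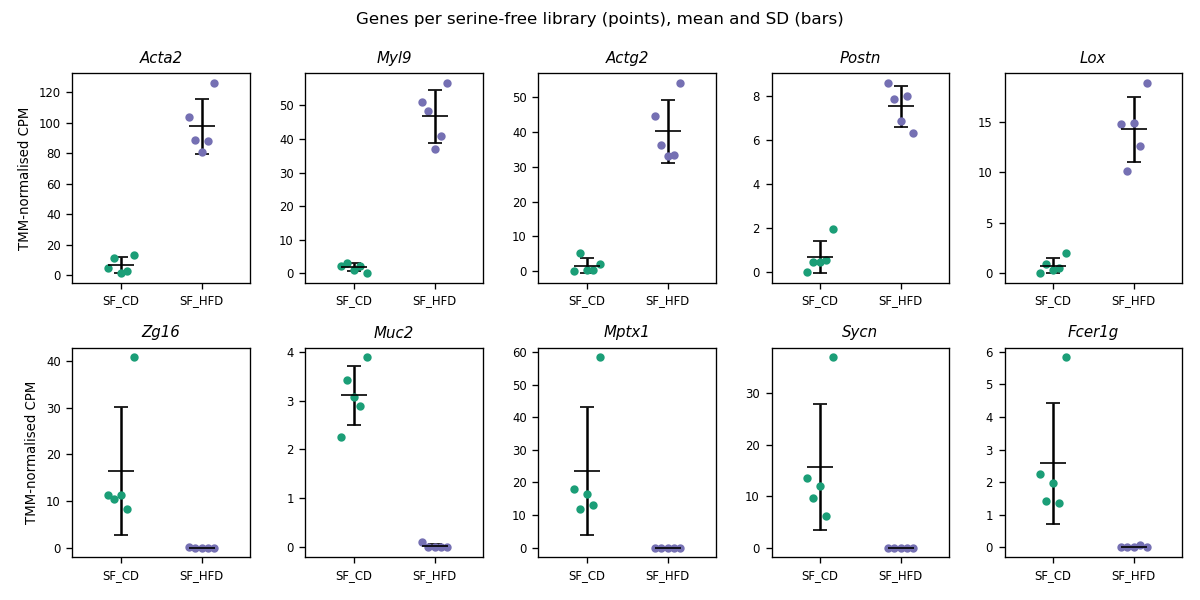
TMM-normalised CPM (y axes, each with its own scale) of 10 genes in the SF_CD and SF_HFD libraries (x axes). Points are libraries, horizontal bars the mean and error bars the SD (n = 5 each). Acta2 was at 97.6 CPM in SF_HFD and 6.79 CPM in SF_CD, and Mptx1 and Sycn were at 0 in all SF_HFD libraries.

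Several other genes that fell were high in only part of the SF_CD libraries. Igf1, a growth factor, was at 255 ± 321 CPM in SF_CD and 2.87 ± 3.37 CPM in SF_HFD (edgeR adjusted p = 0.0469). Itga4, an integrin chain, was at 21.3 ± 27.0 CPM against 0.178 ± 0.270 CPM, Fetub at 25.6 ± 31.3 CPM against 0.396 ± 0.489 CPM, Igfbp5 at 25.0 ± 27.4 CPM against 0.434 ± 0.657 CPM and Hs3st3b1 at 30.0 ± 34.8 CPM against 1.12 ± 0.805 CPM. Without the SF_CD library 4, the SF_CD means of Igf1 and Fetub were 153 and 13.04 CPM, and without the SF_CD library 5 those of Itga4 and Hs3st3b1 were 12.5 and 17.6 CPM. Without the SF_HFD library 3, the SF_HFD means of Igf1, Itga4, Fetub and Igfbp5 were 1.39, 0.0604, 0.218 and 0.173 CPM. All 5 genes were highest in the SF_CD libraries 4 and 5, and each call was lost in 10 to 12 of 19 other settings. Hdc, the histidine decarboxylase, was at 102.6 CPM in the SF_CD library 4 and 46.7 CPM in the SF_CD library 5, at 0 to 1.82 CPM in the other 3 SF_CD libraries and at 0 to 1.26 CPM in SF_HFD. Its groups overlapped, and its call was lost in 10 settings. It was the 1 gene of the neutrophil list that fell among 4 measured (camera adjusted p = 0.890). Fcer1g, an immunoglobulin receptor chain of myeloid cells, was at 2.57 ± 1.87 CPM in SF_CD with 1 count in SF_HFD, a ratio of 61.4 (interval 10.5 to 2472). Its edgeR adjusted p was 0.0524 without the SF_HFD library 1 and 0.0854 without the SF_HFD library 4. It was the 1 gene that fell among the 6 measured in the macrophage and dendritic list (median -1.08, camera adjusted p = 0.0466, adjusted p = 0.359 with an estimated correlation). Adjusted over the list alone, 1 of them rose and 2 fell. The call of this list was lost in 8 of 17 other settings, with camera adjusted p of 0.0624 with RLE normalization, 0.169, 0.174 and 0.0805 without the SF_CD libraries 1, 2 and 3, and 0.0547, 0.115, 0.128 and 0.0663 without the SF_HFD libraries 1, 2, 3 and 4.

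Ndufb4c had the smallest adjusted p (3.56e-05). It had 0 counts in SF_CD and 2629 in SF_HFD. The gene (chromosome 15, 73809507 to 73809896), labelled a processed pseudogene, is a near-identical copy of Ndufb4, a subunit of respiratory complex I. All 360 of the 31-base words of the annotated transcript of Ndufb4c also occur in Ndufb4, so its count is uncertain. The summed level of both genes was 468 ± 82.2 CPM in SF_HFD and 456 ± 186 CPM in SF_CD (exact two-sided permutation test, p = 0.952).

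The remaining lists called by camera had no member past the threshold over all genes. The revival stem and fetal-like list rose (32 of 34 measured, 26 with a positive log2 fold change, median 0.53, camera adjusted p = 0.00762, but 0.675 without the 3 libraries under 1000000 counts), with an adjusted p of 0.651 with an estimated correlation and 0 members past the threshold adjusted over the list alone. Its most abundant members did not pass the test: Anxa1 was at 3099 ± 1003 CPM in SF_HFD and 3825 ± 1999 CPM in SF_CD, and S100a6 at 2638 ± 562 CPM against 2631 ± 1428 CPM. Clu, a marker of revival stem cells, was at 72.6 ± 55.1 CPM against 82.8 ± 35.8 CPM (edgeR adjusted p = 0.919), and Ly6a at 1951 ± 399 CPM against 1611 ± 811 CPM (edgeR adjusted p = 0.812). The pan-epithelial list rose (14 of 15 measured, median 0.69, camera adjusted p = 0.00335, but 0.0547 without the SF_HFD library 1; adjusted p = 0.642 with an estimated correlation), with Krt19 at 2307 ± 497 CPM against 1648 ± 975 CPM. The NF-kB list rose (median 0.67, camera adjusted p = 0.00355, but 0.0536 without the SF_HFD library 4; adjusted p = 0.642 with an estimated correlation), and 2 members rose adjusted over the list alone. Its most abundant members did not pass the test. Nfkbia was at 110.0 ± 28.7 CPM against 228 ± 343 CPM, and its log2 fold change was -1.02 with all libraries and 0.60 without the SF_CD library 1. For Tnfaip2 these were -1.40 and 1.47. The Wnt target list fell (median -0.54, camera adjusted p = 0.0233; adjusted p = 0.651 with an estimated correlation; 2 fell adjusted over the list alone), as did the proliferation list (median -0.32, camera adjusted p = 0.0123; adjusted p = 0.836 with an estimated correlation). The Wnt target call was lost without the SF_CD library 1 (camera adjusted p = 0.123), 4 (0.0921) or 5 (0.0979) and without the SF_HFD library 1 (0.0815), 4 (0.0533) or 5 (0.0592), and the adjusted p was 0.851 without the 3 libraries under 1000000 counts. The Wnt targets Sox4 and Ccnd1 were at 911 and 854 CPM in the SF_CD library 1 and at 576 and 522 CPM in the SF_CD library 5, the libraries with the most ribosomal RNA, and at most at 234 and 135 CPM in the other SF_CD libraries. Their log2 fold changes were -1.16 and -0.64 with all libraries and 0.45 and 0.92 without the 3 libraries under 1000000 counts. The proliferation call was lost without the SF_CD library 2 (0.174) or 4 (0.0535) and without the SF_HFD library 1 (0.137) or 4 (0.134). Top2a was at 323 ± 189 CPM against 675 ± 329 CPM and Mki67 at 98.8 ± 92.8 CPM against 126 ± 59.6 CPM, neither past the threshold. The SF_HFD mean of Mki67 was 57.7 CPM without the SF_HFD library 2.

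Genes of ceramide and serine metabolism did not pass the test. In the simulation this comparison recovered 0% of 2-fold and 42.4% of 4-fold changes, so changes of this size cannot be excluded. Sptlc1 and Sptlc2, the subunits of the enzyme that starts sphingolipid synthesis from serine, had log2 fold changes of 0.30 ± 0.40 and 0.38 ± 0.34 (edgeR adjusted p = 0.833 for Sptlc1, and Sptlc2 also missed the threshold). Among 14 measured genes of ceramide synthesis none was called and 1 fell adjusted over the list alone (camera adjusted p = 0.898), nor was any of 20 of ceramide turnover (0.754). Phgdh and Psat1, enzymes of serine synthesis, had log2 fold changes of -0.07 ± 0.38 and 0.04 ± 0.37, and the serine and one-carbon list had a camera adjusted p of 0.898. Lgr5, a marker of crypt base stem cells, was at 6.56 ± 5.40 CPM in SF_HFD and 48.9 ± 47.7 CPM in SF_CD (edgeR adjusted p = 0.148). The SF_CD mean was 30.4 CPM without the SF_CD library 5, and the SF_HFD mean was 4.28 CPM without the SF_HFD library 2. The log2 fold change of Lgr5 lay between -3.31 and -1.33 in 19 other settings. Its groups overlapped. The SF_CD libraries 1, 4 and 5 were at 40.6, 64.7 and 123 CPM and the SF_CD libraries 2 and 3 at 11.5 and 4.90 CPM. The SF_HFD libraries were at 1.26 to 15.7 CPM. Lgr5 was called with DESeq2 (adjusted p = 0.00834) and without the SF_CD library 3, the lowest of its group (edgeR adjusted p = 0.0415). Ascl2 was at 19.7 ± 7.51 CPM against 15.5 ± 16.8 CPM, with an SF_CD mean of 9.28 CPM without the SF_CD library 2. Cpt1a, which admits fatty acids to mitochondria, was at 14.7 ± 8.12 CPM against 24.8 ± 13.6 CPM, and H2-Ab1 at 3.01 ± 1.77 CPM against 3.71 ± 4.38 CPM, neither past the threshold. The SF_CD mean of H2-Ab1 was 1.98 CPM without the SF_CD library 3. Olfm4, Pdk4 and Angptl4 had too few counts to be tested.

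The SF_CD libraries 1 and 5 stood apart in RNA content. Ribosomal RNA took 22.0% and 14.5% of their counts, against 2.08% to 7.19% in the other serine-free libraries, and Malat1, a nuclear RNA, took 12.1% of the SF_CD library 1. The SF_HFD library 5, also under 1000000 counts, had 2.97% ribosomal RNA. Without the 3 libraries under 1000000 counts, 26 genes were called, 19 of them among the 38, and Acta2 had a log2 fold change of 4.08 with an edgeR adjusted p of 0.0701. The planned model of all 18 libraries called 109 genes, DESeq2 382, limma-voom 173 and a model with no filter 78, and the count was 88 without the SF_CD library 2, 24 without the SF_CD library 4, and 19, 16 and 23 without the SF_HFD libraries 2, 4 and 5. At least as many lists as the 9 called by camera arose in 13 of 100 splits of these libraries, the real one included.

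HFD was compared with CD to show the effect of the high fat diet with serine present. The row labels of these 8 libraries do not name the genes their counts come from, so only rows without gene names could be compared. Actb, Gapdh, Eef1a1 and Epcam had 0 counts in all 8 libraries, while the lowest serine-free library had 1830, 781, 503 and 106 counts. Of 93 genes that code for ribosomal, respiratory, mitochondrial and epithelial proteins, 59 were at 0 in all 8 libraries, and 92 were detected in all 10 serine-free libraries. Rows labelled as processed pseudogenes held 26.8% to 29.4% of the counts in these libraries and at most 0.625% in the serine-free ones. Over rows, the median Spearman correlation was 0.882 between libraries of CD and HFD and 0.0247 between these and the serine-free libraries.

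Of 10341 rows tested in the 8 libraries, 184 were higher and 269 lower in HFD (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). The median change was 1.76-fold among the higher rows and 2.30-fold among the lower rows. Of the 453 rows, 423 had groups that did not overlap. Over all rows the share was 13.7%, against 3.57% from chance. The planned model of all 18 libraries called 4 rows, DESeq2 874, a model with no filter 990 and a 2-fold minimum 223, and upper quartile normalization gave 252 higher and 238 lower rows. The count was 157, 39 and 1161 without the CD libraries 1, 2 and 3, and 50, 110, 296 and 79 without the HFD libraries 1, 2, 3 and 4.

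The comparisons of SF_HFD with HFD and of SF_CD with CD, and the interaction of diet with serine, are not reported, because a row does not hold the same gene in the libraries with and without serine. For the same reason no correlation of the fold changes of the high fat diet with and without serine is reported. Serine in the diet was also split in the same way as the naming of the libraries.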

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

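The tests of row order, depth, cell mixture and shared reads were chosen after the results were seen, and the genes given per library for the cell mixture after their values were seen. The tests of other splits of the samples were planned. The score of the macrophage list replaced an earlier comparison of list medians (pan-epithelial median 0.69). The evenness test was the second measure tried: a first one, the SD of log2 CPM over all 5 SF_HFD libraries, gave mixed results for single genes. A library far from the other 4 of its group was found in 28 of 177 groups of values tested. Chance gives about 1 in 20 groups for normally distributed values. A single count was enough for a flag where the other libraries were at 0. The 28 flags were more than the 8.85 expected at 1 in 20. The values need not be normally distributed, so this number alone does not decide whether libraries were outlying. Of the 13 flags in SF_CD, 6 were in library 1 and 5 in library 5, and 15 flags were in SF_HFD.

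In SF_CD, library 1 stood apart in the share of Malat1 (12.1% of counts) and, in CPM, in Cd44 (1096), Slc12a2 (322), Nfkbia (836), Tnfaip2 (699) and Lipe (11.3). Library 5 stood apart in Postn (1.95 CPM), Mptx1 (58.4), Sycn (37.0), Zg16 (40.9) and Fcer1g (5.84). Library 2 stood apart in Ido1 (2.31 CPM) and library 3 in Nupr1 (3902 CPM). In SF_HFD, library 1 stood apart in Myof (65.0 CPM), Lgals4 (4409), Pparg (79.6), Ceacam10 (1.27), Zg16 (0.0905) and Muc2 (0.0905). Library 2 stood apart in Slc12a2 (597 CPM) and Mki67 (263), library 3 in Igf1 (8.79) and Itga4 (0.647), library 4 in Tnfaip2 (141) and Fcer1g (0.0755), and library 5 in Psat1 (222), Hdc (1.26) and Lipe (11.4). The low values of Zg16, Muc2, Fcer1g, Hdc and Itga4 in SF_HFD rest on few counts.

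Of 100 splits of the 10 serine-free libraries, only the real one called as many as 38 genes, and the highest of the others called 1. For HFD against CD, only the real one of 56 splits called as many as 453 rows, and the highest of the others called 51. A random split of these libraries is therefore unlikely to give as many calls. The splits cannot exclude a difference between animals, cultures or preparations that runs with the groups. The labels do not say that the libraries of a group come from separate animals or cultures. Chance could not be excluded for the number of lists called. At least the 9 of the real split arose in 13 of 100 splits, the real one included, and the highest of the others gave 13.

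Genes that every cell uses were at 0 in the CD and HFD columns. Too few counts cannot account for this, since the shallowest serine-free library detected 92 of the 93 genes. A candidate explanation is that these columns were joined to the row labels in another order. When their rows were taken in the order of the table's symbols sorted by letter, the correlation of log2 summed counts with the serine-free libraries, across rows that are not independent replicates, was 0.958, against 0.0282 as deposited and at most 0.00933 in 100 random orders. The order was found from these data and held (a correlation above 0.5) in 107 of 109 windows of 500 rows, not in all, so no gene was named from it, and no biological explanation was tested.

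Smooth muscle and fibroblast lists were higher in SF_HFD. A lower share of epithelial cells would raise other cell types alike only if these all respond in the same way, which was not tested. The score of both lists minus that of the macrophage list (6 measured genes) was 3.37 higher (log2, n = 5 each). The exact two-sided permutation test gave p = 0.00794, and p = 0.0286 in the 7 libraries over 1000000 counts, each the smallest p possible. The score of both lists alone, 2.66 higher, gave the same p-values, so the subtraction adds no separate evidence. The macrophage score itself fell by 0.71 (exact permutation p = 0.0397, but 0.171 in the 7). The pan-epithelial score was 0.687 higher (exact permutation p = 0.0556, and 0.286 in the 7). These scores do not decide whether the share of epithelial cells differed. Stromal cells or their RNA in the SF_HFD libraries remain possible and cannot be told apart from an effect of the diet on the cells themselves, which was not tested, since the higher mean of 16 of 17 measured members restates the pattern and decides nothing. In raw CPM over all 5 libraries, the groups did not overlap in Acta2 (80.8 to 137 in SF_HFD and at most 13.4 in SF_CD), Myl9, Actg2 and Dcn (23.8 to 45.4 and 2.24 to 22.9), Col1a1 (17.8 to 49.5 and 1.25 to 22.9), Col1a2 and Sparc overlapped only through the SF_CD library 5 and Col3a1 only through the SF_CD libraries 1 and 5, while Vim overlapped widely (5.50 to 86.5 and 4.88 to 71.5), and a cell sort such as the design text describes could remove stromal cells. Of the 17 members, the 13 at 5 CPM or more had a median variance of 2.50 times counting noise between the 4 deeper SF_HFD libraries. Matched lists were at 15.2 (percentile 0 among 10000 lists). A shared source of RNA spread evenly could give this, but the members differed. Cnn1, Postn, Tagln, Mfap5, Col1a2, Col3a1 and Dcn were at 0.717 to 2.50. Actg2, Col1a1, Myl9, Sparc and Acta2 were at 8.76 to 11.1, and Gsn, at 136, lay far above the matched lists.

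Ndufb4c was at 0 in SF_CD and present in SF_HFD. A candidate explanation is reads shared with Ndufb4, since 100% of its 31-base words (percent of the 31-mers of Ndufb4c) also occur there. Ndufb4c held 13.02% to 14.8% of the summed counts in the SF_HFD libraries and 0% in SF_CD. The summed level was 468 CPM in SF_HFD and 456 CPM in SF_CD (exact two-sided permutation test, p = 0.952). Why the share lay in this narrow range in SF_HFD and was 0 in SF_CD was not tested. With all words shared, these counts cannot decide whether the diet changed Ndufb4c itself. Any other difference that runs with the groups also stays open, and whether it bears on other genes was not tested.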

How the results depend on the processing

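The model without the 3 libraries under 1000000 counts was chosen after the data were seen, as was the reporting of models of only the libraries compared. For SF_HFD against SF_CD (38 genes), the count was 78 with no filter, 382 with DESeq2, 173 with limma-voom and 109 with all 18 libraries in 1 model. It ranged from 16 to 88 when 1 library was left out, with 88 without SF_CD 2, 24 without SF_CD 4, 19 without SF_HFD 2, 16 without SF_HFD 4 and 23 without SF_HFD 5. The share of higher genes was 47.4% and 57.8% with limma-voom, 22.5% with DESeq2, 30.8% with no filter, 34.9% with all 18 libraries and 61.5% without the 3 shallow libraries. When 1 library was left out it ranged from 19.2% without SF_CD 3 to 68.8% without SF_CD 5. DESeq2 moved the median log2 fold change of all genes to -0.32. For HFD against CD (453 rows), the count was 223 with a 2-fold minimum, 990 with no filter, 874 with DESeq2 and 4 with all 18 libraries. It ranged from 39 to 1161 when 1 library was left out, with 157 without CD 1, 39 without CD 2, 1161 without CD 3, 50 without HFD 1, 110 without HFD 2, 296 without HFD 3 and 79 without HFD 4. The share of higher rows was 40.6%, 51.4% with upper quartile normalization, 18.6% with the replicate block and 25% of 4 rows with all 18 libraries. When 1 library was left out it ranged from 15.4% without CD 2 to 48.8% without CD 3, with 26.8% without CD 1, 30% without HFD 1 and 25.3% without HFD 4. The 9 lists became 0 with an estimated correlation and 1 with fry, and stayed between 6 and 12 otherwise. Causes were not tested. Each left-out library lowers the number of samples, but the count also rose in some of these settings, such as without CD 3 and without SF_CD 2.

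Samples share replicate numbers across groups. With the replicate block, 22 genes were called for SF_HFD against SF_CD, 20 of them among the 38, and 97 rows for HFD against CD, 69 of them among the 453. Same-numbered libraries did not deviate together: the correlations of their deviations were -0.0738, -0.211, 0.136, -0.00086 and -0.0318 in the serine-free groups and 0.106, -0.0707 and -0.00615 in the others, and not every library correlated best with its own number. Signs turned under the block for uncalled genes, with log2 fold changes of Myof 0.18, Ucp2 0.021, Msmo1 0.038, Nfkbia 0.14, Tnfaip2 0.59 and H2-Ab1 0.035, and for uncalled lists, with adjusted p of crypt base stem cell 0.908, fatty acid oxidation 0.908, fatty acid synthesis 0.900 and immediate early 0.908.

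Of 23 named genes that were called, 11 stayed past the threshold in all settings run, Ndufb4c (whose count is uncertain), Lox, Myl9, Postn, Ctla2a, Col5a2, Mptx1, Sycn, Zg16, Muc2 and Spink1. The calls of Acta2 (1 setting), Ceacam10 (2), Fcer1g (3), Actg2 (4), Mfap5 (9), Fetub and Hdc (10), Itga4 and Hs3st3b1 (11), and Ido1, Igf1 and Igfbp5 (12) were lost in the others. Over 17 other settings per list, the macrophage and dendritic call was lost in 8, the Wnt target call in 7, the proliferation call in 4, and the pan-epithelial, NF-kB and revival stem calls in 1 each. The smooth muscle, fibroblast and goblet calls were lost in 0 of these 17, all with the preset correlation. Uncalled lists gained a call in some of the 17, all with the preset correlation: oxidative phosphorylation in 7, interferon in 5, epithelial-mesenchymal transition in 4, and cholesterol synthesis and YAP target in 1 each. Of uncalled named genes, Btg2 gained a call in 3 of 19 settings (adjusted p of 0.00793 with DESeq2, 0.0323 without SF_CD 2 and 0.0459 without SF_CD 3), Lgr5 in 2 (0.00834 with DESeq2 and 0.0415 without SF_CD 3), and Cenpf and Mmp7 in 1 each (0.0294 with DESeq2). None of the 23 genes or of the 9 lists called turned direction, but 30 named genes and 14 lists that were not called did in at least 1 setting. Depth limits the SF_CD libraries 1 and 5 and the SF_HFD library 5, where 3 counts are 5.73 CPM in SF_CD 5 and 4.12 CPM in SF_HFD 5, above the level of many genes that changed.

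With DESeq2, the log2 fold changes of opposite sign were S100a6 -0.043 and Psat1 -0.0023. With RLE normalization, the log2 fold changes of opposite sign were S100a6 -0.043. With limma-voom, the log2 fold changes of opposite sign were S100a6 -0.058, Cd44 0.13, Ccnd1 0.65, Sox4 0.36, Myof 0.59, Asah1 -0.029, Psat1 -0.30, Fdps -0.18, B2m 0.022, Nfkbia 0.63, Tnfaip2 1.37, Ldha -0.031, Cox4i1 -0.047, mt-Cytb -0.060 and Car2 -0.071. With all 18 libraries, the log2 fold changes of opposite sign were S100a6 -0.032 and Psat1 -0.028. Without the 3 shallow libraries, the log2 fold changes of opposite sign were S100a6 -0.25, Cd44 0.31, Ccnd1 0.92, Sox4 0.45, Myof 0.59, Asah1 -0.43, Psat1 -0.49, Fdps -0.33, Bst2 -0.083, Nfkbia 1.04, Tnfaip2 1.39, Ldha -0.34, Ndufa4 -0.15, Cox4i1 -0.090, mt-Cytb -0.29, Car2 -0.10, Ascl2 -0.31 and Mki67 0.29. Over the left-out libraries, uncalled genes whose sign turned ranged in log2 fold change as follows: Acer3 -0.43 to 0.11, Ascl2 -0.13 to 0.92, Car1 -0.33 to 2.003, Car2 -0.18 to 0.72, Ccnd1 -0.87 to 0.032, Clu -0.71 to 0.072, Fdps -0.21 to 0.38, H2-Ab1 -1.02 to 0.20, Ldha -0.057 to 0.45, Lgals4 -0.19 to 1.38 and Lipe -0.43 to 0.22. The others were Msmo1 -0.31 to 0.15, mt-Cytb -0.046 to 0.32, Myof -0.46 to 0.37, Nfkbia -1.34 to 0.60, Phgdh -0.28 to 0.077, Pmaip1 -0.86 to 0.057, Psat1 -0.17 to 0.19, S100a6 -0.14 to 0.39, Tecr -0.34 to 0.0075, Tnfaip2 -2.14 to 1.47 and Ucp2 -0.22 to 0.11.

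With RLE normalization, the adjusted p of lists of opposite direction were fatty acid oxidation 0.973 and fatty acid synthesis 0.973. With no filter, the adjusted p of lists of opposite direction were crypt base stem cell 0.656, fatty acid oxidation 0.847, fatty acid synthesis 0.769 and deep crypt secretory 0.920. With all 18 libraries, the adjusted p of lists of opposite direction were crypt base stem cell 0.784 and fatty acid synthesis 0.784. Without the 3 shallow libraries, the adjusted p of lists of opposite direction were crypt base stem cell 0.227, ceramide turnover 0.851, fatty acid oxidation 0.373, fatty acid synthesis 0.952, oxidative phosphorylation 0.0307 and ribosomal protein 0.00941. Over the left-out libraries, the adjusted p of uncalled lists that turned ranged as follows: absorptive colonocyte 0.119 to 0.996, ceramide synthesis 0.697 to 0.987, crypt base stem cell 0.513 to 0.998, fatty acid synthesis 0.697 to 0.998, immediate early 0.269 to 0.987, mitochondrially encoded 0.583 to 0.996, neutrophil 0.539 to 0.989, oxidative phosphorylation 0.00379 to 0.963, fatty acid oxidation 0.612 to 0.998, ribosomal protein 0.208 to 0.991, serine and one-carbon 0.397 to 0.998 and YAP target 0.170 to 0.989. The oxidative phosphorylation and ribosomal protein lists passed the threshold in the opposite direction without the 3 shallow libraries.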

Other observations

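Lists that camera did not call with all libraries covered metabolism and other cell types. The fatty acid oxidation list had a median log2 fold change of 0.01 (camera adjusted p = 0.991), fatty acid synthesis 0.04 (0.986) and cholesterol synthesis -0.17 (0.299). The amino acid response list had a median of 0.08 (0.799), and Nars, a tRNA ligase, was at 580 ± 92.4 CPM in SF_HFD and 1201 ± 587 CPM in SF_CD (edgeR adjusted p = 0.241). Glycolysis and hypoxia genes had a median of 0.18 (0.403), oxidative phosphorylation 0.17 (0.0643), mitochondrially encoded genes -0.01 (0.903) and ribosomal proteins 0.03 (0.890). The oxidative phosphorylation list had an adjusted p of 0.995 with an estimated correlation. With the preset correlation it was called, upward, in 7 of 17 other settings, with adjusted p of 0.00606 with no filter, 0.0275 with all 18 libraries, 0.00379, 0.00800 and 0.0171 without the SF_CD libraries 2, 3 and 4, and 0.0114 and 0.0417 without the SF_HFD libraries 2 and 4. It turned downward without the SF_CD library 1 (0.963) and without the 3 libraries under 1000000 counts (0.0307). The interferon list had a median of -0.33 (0.0772), the p53 list 0.26 (0.402), the immediate early list 0.25 (0.898) and the YAP target list -0.18 (0.890). The interferon list had an adjusted p of 0.651 with an estimated correlation. With the preset correlation it was called, downward, in 5 of 17 other settings, with adjusted p of 0.0367 with no filter, 0.0401 with all 18 libraries, 0.0309 and 0.0321 without the SF_CD libraries 3 and 5, and 0.0193 without the SF_HFD library 3. Without the 3 libraries under 1000000 counts, the YAP target list was called upward (0.0366) and the cholesterol synthesis list downward (0.00804). With an estimated correlation and all libraries, these lists had an adjusted p of 0.995 and 0.836. Absorptive colonocyte genes had a median of 0.24 (0.898), with Car1 at 1181 ± 1617 CPM against 638 ± 842 CPM. The SF_HFD mean of Car1 was 510 CPM without the SF_HFD library 1, and its SF_CD mean was 293 CPM without the SF_CD library 3. Crypt base stem cell genes had a median of 0.16 (0.986), deep crypt secretory and Paneth genes -0.18 (0.440; adjusted over the list alone, 2 rose and 3 fell) and adipocyte genes 0.19 (0.577). Genes of T cells, B cells, endothelium, erythroid cells, hepatocytes, tuft cells, enteroendocrine cells and antigen presentation by class II molecules had at most 3 measured members and were not tested. The test's direction was opposite to the median for the YAP target and mitochondrially encoded lists (up) and for the absorptive, crypt base stem cell, ceramide synthesis, serine and neutrophil lists (down).

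In CPM of the raw totals, Zg16 was at 8.41 to 9.98 CPM in the 3 SF_CD libraries above 1000000 counts and at 8.41 to 40.1 CPM in all 5. Mptx1 was at 11.2 to 14.6 CPM and 11.2 to 57.3 CPM, and Sycn at 6.39 to 10.6 CPM and 6.39 to 36.3 CPM. The highest value of each was in the SF_CD library 5. A shared source of RNA spread evenly was tested only for stromal genes in SF_HFD, not for these genes in SF_CD. It cannot be told apart here from an effect of the diet.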
